A study of Mus musculus with 6 samples.

How the data were processed

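RNA of flow-sorted GATA1s megakaryocyte progenitors was hybridised to Affymetrix mouse arrays, with 3 samples from adult bone marrow and 3 from fetal liver, as the labels state. The deposited values are linear intensity signals, 1 per probe set and array, made by the authors with MAS5, per the submitters' processing notes; its version is not given in the sources used here. On every array the mean after trimming 2% at each end was 500, as measured in the deposited values. MAS5 signals have no offset added and spread widely at low intensity, so large ratios rest on noisy low values. The labels call the samples biological replicates and do not say how many animals each came from, so p-values measure the spread between these samples. The number of arrays limits the precision: with 3 against 3, an exact permutation test of a single value cannot go below 0.1, and no such test is used. No pair of arrays had identical values, and 0 columns were left unmapped to a sample.

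The table held 45101 probe sets, of which 64 were controls. Of the other 45037, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none listed. Symbols were checked by Entrez identifier against a RefSeq gene table of assembly GRCm38.p6, where 34754 matched and 0 needed updating; no coordinates are given. Probe sets with several genes or none were not used to name a gene. The 18193 named genes were covered by 1 or more probe sets. Gene list members were matched by current symbol, or by a synonym only where it was unique and was not itself a current symbol; 576 of 628 list memberships were found, and the others were not analysed here. This matching rule was corrected after a first run in which 3 names had been assigned to wrong genes, and the imprinted gene list passed its test only after the correction.

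Signals were log2-transformed with no offset. Probe sets were kept when their mean log2 signal over all 6 arrays was above the 40th percentile, a signal of 22.9, which left 27022 probe sets. For each of the 11645 genes among them, the probe set with the highest mean was used. Where several probe sets of a gene were tested (5959 genes), 21 genes had probe sets called in both directions. A further 972 of 4592 filtered probe sets without a single gene were called. limma (version 3.58.1, R 4.3.3) fitted tissue as the only term, with 4 residual degrees of freedom and an intensity-trended variance prior, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Tests on 30 gene lists used limma's camera with a preset correlation of 0.01, adjusted over the lists; camera with an estimated correlation and fry were alternatives. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

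The comparison, lists, naming rule and most alternatives were fixed before the data were examined. Named genes were the sort markers and Gata1, and per direction the 8 called genes with the largest log2 fold change of at least 1. Those had separated arrays and a higher-group mean above the median of all tested genes, and clone, model and multi-gene names were passed over. Up to 4 members per list with the smallest adjusted p, the 3 brightest members of each cell-type list and any member of a list with under 6 tested members were also named. A background level was chosen after seeing the data: the 95th percentile of 27 unspiked bacterial control probe sets over all arrays, a signal of 10.6. Where a group's geometric mean lay below it, the fold is given as at least the ratio to the geometric mean of that group with each array below the level set to it. Alternatives tried were no filter, a filter at the 60th percentile, quantile normalization, median centring, an offset at the 25th percentile (7.54), the mean of a gene's probe sets, each probe set on its own, no variance trend, a robust prior, array weights, a replicate block, ordinary t statistics, leaving out each array, and a floor at the control level, which was added after seeing the data.

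The test was checked on simulated data of 11645 genes with 200 changed. It recovered 68% of 100 genes changed 2-fold and 87% of 100 changed 4-fold, with 7 unchanged genes called. With no gene changed it called 0 genes and 0 lists, and with 1 list shifted it called that list alone. Simulated noise was independent between genes, so this check does not cover lists whose members vary together. In the data the estimated correlation of list members reached 0.68, for immediate early and heat shock genes. The simulated share of changed genes was also far below the 36.1% of genes called in the data.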

Results

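RNA from megakaryocyte progenitors of C57BL/6 mice with the GATA1s genotype was measured on 6 expression arrays. GATA1s is the amino-terminally shortened form of the transcription factor GATA1, which directs megakaryocyte and erythroid development. The progenitors were sorted by flow cytometry as lineage-negative, Sca-1-negative cells carrying c-kit, CD150 and CD41. Bone marrow of adults aged 12 to 18 weeks gave 3 arrays, and fetal liver at E13.5 gave 3. The question was how progenitors of this genotype differ between the fetal and the adult tissue. Cells with full-length GATA1 were not analysed here, so no difference below can be assigned to the genotype. Median signal was 65.9 to 74.6 on the bone marrow arrays and 52.0 to 59.1 on the fetal liver arrays. Log2 signals correlated across probe sets, which are not independent replicates, at r = 0.976 to 0.987 within a tissue and 0.878 to 0.906 between tissues.

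Of the 3 sort marker genes tested, only Kit passed the test between tissues. Itga2b, which encodes CD41, had a signal of 4418 ± 540 in bone marrow and 4521 ± 1049 in fetal liver (SD, n = 3 each). Its log2 fold change, fetal liver minus bone marrow throughout, was 0.01 ± 0.17 (SE, adjusted p = 0.963). Slamf1, which encodes CD150, had a log2 fold change of -0.07 ± 0.34 (adjusted p = 0.886), and fetal liver replicate 1 decided that value. Without that array it was 0.42 (adjusted p = 0.0242). Kit fell from 1845 ± 59.0 in bone marrow to 1225 ± 295 in fetal liver (log2 fold change -0.62 ± 0.16, adjusted p = 0.0141). Gata1 was higher in fetal liver, at 4188 ± 372 against 2999 ± 476 (log2 fold change 0.49 ± 0.12, adjusted p = 0.0138). With ordinary t statistics the calls of Kit (adjusted p = 0.0999) and Gata1 (0.0975) were lost.

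Of 11645 genes tested with limma, 4208 differed between the tissues, 2074 higher and 2134 lower in fetal liver. At 2-fold or more the balance moved, with 467 genes higher and 1232 lower. All 3 arrays of one tissue lay above all 3 of the other for 5877 genes (50.5%), against 10% by chance, and for 4154 of the called genes. The direction split depended on scaling: quantile normalization gave 2356 higher and 1924 lower, and median centring gave 3649 higher and 1686 lower. Median centring moved the median log2 fold change of all genes from 0.04 to 0.20, so changes near that size have no settled direction.

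**Figure D1:**
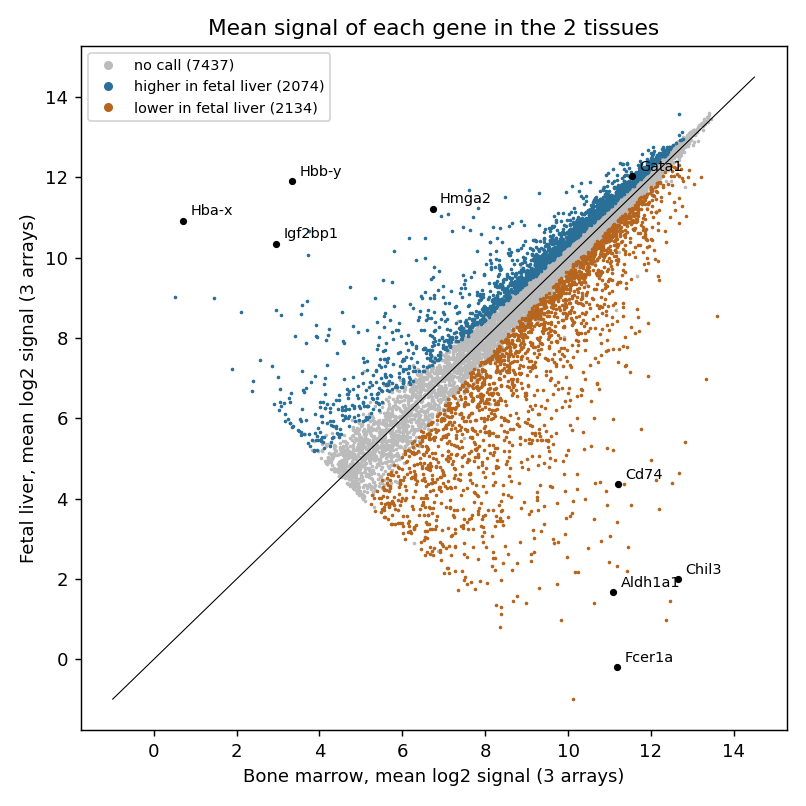
Mean log2 signal of each tested gene over the 3 fetal liver arrays against the 3 bone marrow arrays, one point per gene, with the line of equal signal. Blue points are the 2074 genes called higher and brown points the 2134 called lower in fetal liver; Hba-x and Hbb-y lie far above the line and Fcer1a and Chil3 far below it.

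The fetal liver samples held embryonic globin and fetal RNA-binding protein transcripts that were low or below the control level in bone marrow. Whether the sorted progenitors themselves were the source was not tested. Hba-x, an embryonic alpha-like globin, had a signal of 1938 ± 120 in fetal liver and lay below the control level in bone marrow, a difference of at least 182-fold (adjusted p = 5.85e-07). Hbb-y, an embryonic beta-like globin, was at least 272-fold higher (adjusted p = 2.98e-06; 1 of 3 bone marrow arrays below the control level), and Igf2bp1 at least 123-fold higher (adjusted p = 4.98e-07). Hmga2, a chromatin protein repressed by let-7 microRNAs, rose from 115 ± 51.2 to 2422 ± 467 (log2 fold change 4.49 ± 0.33, adjusted p = 1.38e-05). Igf2bp3 rose from 56.2 ± 7.46 to 1148 ± 86.5 (log2 fold change 4.36 ± 0.17). Tnni1, Dlk1 and Hif3a completed the 8 largest rises by the naming rule, which passes over genes of lower signal such as Peg3, with log2 fold changes of 6.93, 6.35 and 4.33; for Tnni1 and Dlk1, 1 of 3 bone marrow arrays lay below the control level. In the list of the fetal Lin28b programme, 7 of 8 tested members were higher and 1, Lin28a, was lower, both over all genes and adjusted over the list alone. Lin28a was named after its value was seen (log2 fold change -5.09). The list median was 5.94, or 4.997 with members below background set to their bounds (camera adjusted p = 2.12e-06; adjusted p = 0.0794 with an estimated correlation).

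Among imprinted genes 6 of 14 were higher in fetal liver and 2 lower, the same counts as adjusted over the list alone. Dlk1 had a log2 fold change of 6.35 ± 0.29, Ndn 2.26 ± 0.17 and Grb10 1.03 ± 0.16, and Peg3 was at least 39.1-fold higher. The list passed camera narrowly (adjusted p = 0.0478, and 0.192 with an estimated correlation). It lost the call under median centring (adjusted p = 0.152), the stricter filter (0.329) and the replicate block (0.0550). Without fetal liver replicate 1 (0.0625) or 2 (0.0984) it was lost too. Its median was 0.34, and ran from 0.16 without bone marrow replicate 1 to 0.79 under quantile normalization. Of 20 genes of IGF, PI3K and mTOR signalling, 3 were higher and 4 lower, also over the list alone (camera adjusted p = 0.454). Igf1r was higher (log2 fold change 0.40 ± 0.08) and Foxo1, a transcription factor inhibited by this pathway, lower (-0.71 ± 0.13), but Foxo1 lost its call with the mean of its probe sets (-0.15, adjusted p = 0.643).

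Interferon-stimulated genes were lower in fetal liver: 30 of 37 fell and none rose over all genes, and 31 fell and 1 rose adjusted over the list alone. The median log2 fold change was -1.25 (camera adjusted p = 1.56e-11; adjusted p = 0.192 with an estimated correlation), and -0.76 over the 27 members left by the stricter filter. Rsad2, an antiviral enzyme, fell from 2971 ± 1264 to 221 ± 29.9 (log2 fold change -3.65 ± 0.31, adjusted p = 3.04e-05). Sp100 fell from 1675 ± 236 to 119 ± 27.1 (-3.83 ± 0.19, adjusted p = 1.68e-06) and Ifi27l2a from 870 ± 224 to 16.9 ± 8.77 (-5.83 ± 0.45, adjusted p = 1.60e-05), with 1 of 3 fetal liver arrays below the control level. On bone marrow replicate 1 the median list member lay 0.36 log2 units below the mean of the other bone marrow arrays. Among components of interferon and innate sensing pathways, 3 of 24 rose and 8 fell, also over the list alone, with a median of -0.16 (camera adjusted p = 0.0163; adjusted p = 0.127 with an estimated correlation). That median was -0.0004 under median centring, -0.09 under quantile normalization and -0.29 with the mean of a gene's probe sets, so its size is not settled. The transcription factors Irf8 and Irf1 had log2 fold changes of -3.77 ± 0.19 and -2.15 ± 0.12, and Socs3, an inhibitor of cytokine signalling, -4.23 ± 0.31. Irf8 is also a member of the granulocyte and monocyte marker list described below, so its fall counts in both lists.

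Antigen presentation genes followed the same direction. Of 13 MHC class I presentation genes 10 fell and none rose, and 12 fell adjusted over the list alone (median -1.39, camera adjusted p = 9.80e-09; adjusted p = 0.113 with an estimated correlation). Nlrc5, the transactivator of class I genes, fell from 2408 ± 232 to 22.3 ± 11.6 (1 of 3 fetal liver arrays below the control level), the immunoproteasome subunit Psmb9 from 3266 ± 115 to 424 ± 67.5, and H2-K1 from 7318 ± 301 to 2103 ± 218. All 8 tested MHC class II genes fell, also over the list alone (median -4.96, camera adjusted p = 2.32e-09; adjusted p = 0.0794 with an estimated correlation). Cd74, the invariant chain, fell from 2382 ± 120 to 21.9 ± 8.49 (log2 fold change -6.86 ± 0.30, adjusted p = 1.01e-06). These genes fell together with markers of granulocytes, macrophages and lymphoid cells, described next.

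Transcripts of other blood lineages were abundant in the bone marrow samples although the gate excluded lineage-positive cells. All 18 granulocyte and monocyte markers were lower in fetal liver, also over the list alone, with a median of -3.69 (camera adjusted p = 1.11e-16; adjusted p = 0.0794 with an estimated correlation). S100a9, a calcium-binding protein of mature granulocytes, had a signal of 12555 ± 1579 in bone marrow and 448 ± 285 in fetal liver. Ngp, a granule protein, fell from 6616 ± 1168 to 25.3 ± 5.92, and the elastase gene Elane from 1991 ± 220 to 38.5 ± 5.21. Mpo and Lyz2 fell less, with log2 fold changes of -0.84 ± 0.11 and -1.46 ± 0.15. Of 9 macrophage markers 8 fell, also over the list alone (median -2.01, camera adjusted p = 9.97e-06; adjusted p = 0.113 with an estimated correlation), with C1qb at -3.53 ± 0.31. Mast cell and basophil markers fell in 6 of 7 cases, also over the list alone (median -3.59, camera adjusted p = 4.75e-04; adjusted p = 0.113 with an estimated correlation). Their median was -0.78 over 12 members with no filter and -0.84 over 3 members with the stricter filter. Fcer1a, the high-affinity IgE receptor chain, was at least 218-fold lower and the basophil protease Mcpt8 at least 80.2-fold lower. Cpa3 fell less (log2 fold change -0.84). Its call was lost under quantile normalization (limma adjusted p = 0.0713) and the replicate block (0.0569), among other settings. Lymphoid markers fell in 10 of 12 cases, also over the list alone. Their median was -4.03 (camera adjusted p = 2.32e-09, and 0.113 with an estimated correlation). Dntt was at -5.55 ± 0.28 and Ebf1 at -5.24 ± 0.30, while Cd79b, at -0.23, was not called. The stricter filter left 3 lymphoid members with a median of -1.94. On bone marrow replicate 1 the median member lay below the other bone marrow arrays by 0.84 log2 units for lymphoid markers and by 0.56 for mast cell and basophil markers, and on fetal liver replicate 1 the latter lay 0.64 above the other fetal liver arrays. The largest falls by the naming rule also included Chil3, Aldh1a1, Wfdc21, Slfn4 and Apol11b, at least 604-fold, 205-fold, 126-fold, 259-fold and 187-fold lower; for Wfdc21 and Apol11b, 2 of 3 fetal liver arrays lay below the control level. Igkv8-30 and Igkv9-120 were among them too, on probe sets that may detect several related immunoglobulin segments, so which segment was measured is uncertain.

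**Figure D2:**
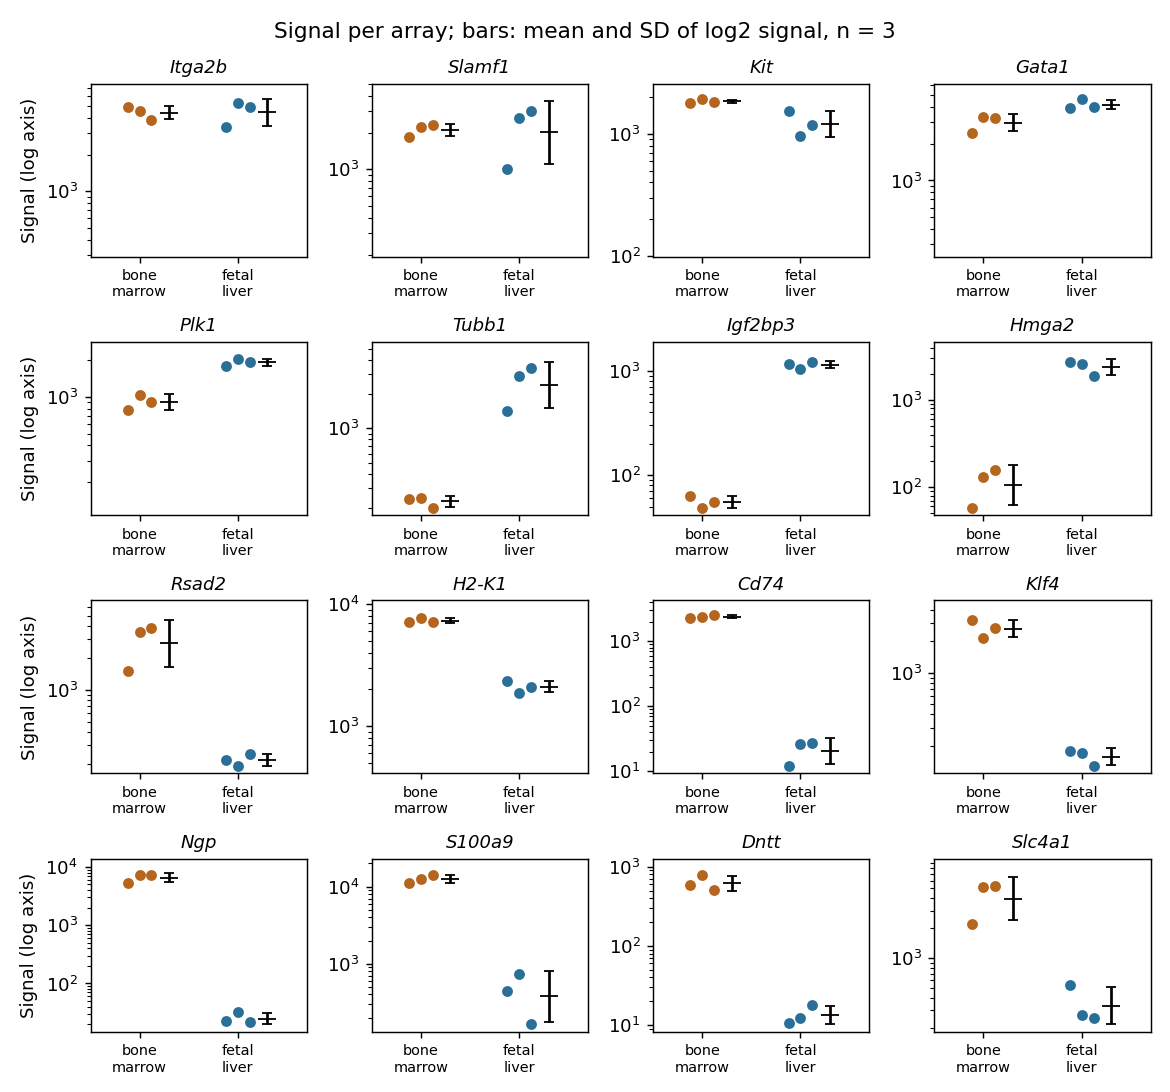
Signal of 16 named genes on each of the 3 bone marrow (brown) and 3 fetal liver (blue) arrays, on log axes that differ between panels, with the mean and SD of log2 signal as bars. Itga2b and Slamf1 overlap between tissues, Plk1, Tubb1, Igf2bp3 and Hmga2 are higher on every fetal liver array, and Rsad2, H2-K1, Cd74, Klf4, Ngp, S100a9, Dntt and Slc4a1 are lower on every fetal liver array.

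Inflammatory and stress-response genes were lower in fetal liver. Of 21 genes of NF-kB and inflammation 18 fell and none rose, and 19 fell adjusted over the list alone (median -1.56, camera adjusted p = 2.71e-09; adjusted p = 0.0794 with an estimated correlation). The cytokine gene Il1b fell from 1295 ± 172 to 105 ± 17.5, and the chemokine gene Ccl4 was at least 37.6-fold lower (2 of 3 fetal liver arrays below the control level). These genes fell together with the granulocyte, monocyte and macrophage markers above. Of 23 immediate early and heat shock genes 19 fell, and 22 adjusted over the list alone (median -1.66, camera adjusted p = 2.23e-09; adjusted p = 0.311 with an estimated correlation). Klf4 fell from 2678 ± 519 to 160 ± 27.3 (log2 fold change -4.06 ± 0.18) and Klf2 from 3388 ± 334 to 313 ± 154 (-3.56 ± 0.30). The mean of this list differed by 1.71 log2 units between fetal liver arrays and by 0.22 between bone marrow arrays, and the median member lay 1.09 higher on fetal liver replicate 1 than on the other fetal liver arrays. p53 targets gave 2 higher and 4 lower of 13, and 5 lower over the list alone (camera adjusted p = 0.135), with Perp at 3.96 ± 0.19 and Trp53inp1 at -3.42 ± 0.27.

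Of 33 mitosis genes 27 were higher in fetal liver and none lower, 28 adjusted over the list alone, by modest amounts (median 0.50, camera adjusted p = 1.79e-10; adjusted p = 0.113 with an estimated correlation). The mitotic kinases Plk1 and Aurka rose from 911 ± 130 to 1926 ± 128 and from 1046 ± 107 to 2171 ± 191, and Cdk1 from 3431 ± 86.4 to 5432 ± 134 (log2 fold change 0.66 ± 0.07). DNA replication genes rose in 12 of 31 cases, also over the list alone (median 0.22, camera adjusted p = 0.00240; adjusted p = 0.323 with an estimated correlation), among them Tk1 at 0.53 ± 0.08; the median was 0.37 under median centring. Of 16 cell cycle brakes and D cyclins 10 fell and 2 rose, also over the list alone (median -0.51, camera adjusted p = 0.0133; adjusted p = 0.192 with an estimated correlation). This list is mixed: the kinase inhibitor Cdkn2c fell (-3.64 ± 0.25), and so did the cycle-promoting genes Cdk6 (-0.54 ± 0.08) and Ccnd2 (-0.98 ± 0.15). With the mean of a gene's probe sets the list median was -0.83 and Cdk6 was at -0.84.

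Megakaryocyte and platelet genes moved in both directions, with 11 of 28 higher and 2 lower, also over the list alone (median 0.35, camera adjusted p = 0.0161; adjusted p = 0.579 with an estimated correlation). Tubb1, the platelet beta-tubulin, rose from 228 ± 24.5 to 2568 ± 1015 (log2 fold change 3.41 ± 0.28), Thbs1 from 665 ± 239 to 3156 ± 368 and Gp9 from 1275 ± 141 to 3047 ± 789, while Selp fell from 2958 ± 271 to 340 ± 161. On fetal liver replicate 1 the median member lay 0.63 log2 units below the other fetal liver arrays, and without that array the list median was 0.56. The list call was lost without fetal liver replicate 2 (adjusted p = 0.0742) or 3 (0.0582) and under quantile normalization (0.0760). Erythroid genes were lower in 9 of 23 cases and higher in 2, also over the list alone, with a median of -0.14 and a mean of -0.87 (camera adjusted p = 0.0196; adjusted p = 0.579 with an estimated correlation). That median ran from -0.33 without bone marrow replicate 1 to 0.01 under median centring. Slc4a1, the red cell anion exchanger, fell from 4229 ± 1739 to 355 ± 164 and Alas2 from 1695 ± 883 to 90.4 ± 32.2. Bone marrow replicate 1 had the lowest bone marrow signals of both, 2225 and 712, and the median erythroid gene lay 0.70 log2 units below the other bone marrow arrays there. Without bone marrow replicate 3 the erythroid call was lost (adjusted p = 0.0718).

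Stem cell and early progenitor genes were lower in fetal liver in 11 of 20 cases and higher in 1, also over the list alone (median -1.76, camera adjusted p = 1.33e-04; adjusted p = 0.113 with an estimated correlation). Cd34 fell from 1814 ± 46.8 to 396 ± 54.4 (log2 fold change -2.20 ± 0.13, adjusted p = 3.36e-06), Hoxa9 from 733 ± 210 to 56.5 ± 31.4 and Hoxa10 from 334 ± 40.03 to 14.6 ± 9.17, with 1 of 3 fetal liver arrays below the control level for Hoxa10. The list median was -0.20 over the 12 members left by the stricter filter. That filter drops members of low mean signal over all 6 arrays, so the size of the list median depends on which members are tested and is not settled. These genes fell together with the granulocyte, mast cell and lymphoid markers above. The exception was Fgd5, which rose (3.49 ± 0.32). Of 21 haematopoietic transcription factors 6 rose and 3 fell, 4 over the list alone, and the list median (-0.05) and mean (0.03) differed in sign (camera adjusted p = 0.753). Gfi1b and Lyl1 rose by 0.75 ± 0.08 and 1.11 ± 0.15, and Spi1 fell (-0.76 ± 0.16).

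Marker lists for the surrounding tissue had few tested members. Endothelial markers were higher in 4 of 6 cases, also over the list alone (median 0.95, camera adjusted p = 0.0161; adjusted p = 0.335 with an estimated correlation; lost with no filter, 0.191), led by Egfl7 at 1.98 ± 0.14 and Kdr at 1.62 ± 0.24. The endothelial median was 0.15 with no filter and 0.49 with the stricter filter or the offset. On fetal liver replicate 1 the median endothelial member lay 0.44 log2 units below the other fetal liver arrays. Of 5 hepatoblast markers 1 was higher and 2 lower, also over the list alone (median 0.17, mean -0.26, camera adjusted p = 0.421), and the median ran from -0.65 with the offset to 0.46 under quantile normalization. It was -0.03 without fetal liver replicate 1 and -0.08 without replicate 3. Afp, a fetal liver protein, was lower in fetal liver progenitors, at 62.6 ± 12.2 against 221 ± 24.8 in bone marrow (log2 fold change -1.84, or -1.04 with the mean of its probe sets). Stromal markers gave 1 higher and 1 lower of 4, also over the list alone (median -0.25, mean 0.35, camera adjusted p = 0.529), with Sparc at 3.61 ± 0.14. Their median ran from -0.77 with the offset to 0.33 with the stricter filter, and was 0.01 without fetal liver replicate 3. Of 4 sex-linked genes 1 was called lower, and none over the list alone (camera adjusted p = 0.705); that gene, Eif2s3y, lost its call under median centring (adjusted p = 0.178), without bone marrow replicate 1 (0.148) or 2 (0.0710) and without fetal liver replicate 1 (0.112) or 2 (0.0960). Xist and the Y-linked genes Eif2s3y and Kdm5d gave signal in both tissues, with Xist at 4680 ± 1494 and 4907 ± 485 and Eif2s3y at 2419 ± 434 and 1809 ± 233 in bone marrow and fetal liver. On bone marrow replicate 1 the median sex-linked gene lay 0.61 log2 units above the other bone marrow arrays. Without that array the log2 fold change of Xist moved from 0.12 to -0.18. The sort marker list had 1 of 3 lower, also over the list alone (camera adjusted p = 0.498).

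Metabolic lists shifted by small amounts, near the size by which scaling moved all genes. Ribosome biogenesis had 9 of 29 genes higher and 1 lower, also over the list alone (median 0.19, camera adjusted p = 0.00457; adjusted p = 0.489 with an estimated correlation; 0.0594 under quantile normalization), and the lower one was Myc (-0.88 ± 0.15). Oxidative phosphorylation had 4 of 24 higher and 0 over the list alone (median 0.18, camera adjusted p = 0.00516; adjusted p = 0.498 with an estimated correlation; 0.131 under quantile normalization). At an adjusted p computed over all genes those 4 were Ndufs1, Ndufs3, Uqcrc1 and Ndufa9, and without bone marrow replicate 1 all 4 lost their calls (adjusted p = 0.0507 to 0.0708). Glycolysis genes were higher in 8 of 15 cases and lower in 1, with 9 higher over the list alone (median 0.28, camera adjusted p = 0.0278; adjusted p = 0.498 with an estimated correlation). That call was lost under quantile normalization (0.0635) and without bone marrow replicate 1 (0.0513) or fetal liver replicate 2 (0.0504). The glucose transporter gene Slc2a1 rose from 2636 ± 307 to 4767 ± 371. Under median centring the medians of ribosome biogenesis, oxidative phosphorylation and glycolysis were 0.35, 0.34 and 0.44, and that of oxidative phosphorylation was 0.11 under quantile normalization and 0.10 without fetal liver replicate 2. Cholesterol biosynthesis gave 6 of 16 higher and 2 lower, 8 higher over the list alone (camera adjusted p = 0.125).

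**Figure D3:**
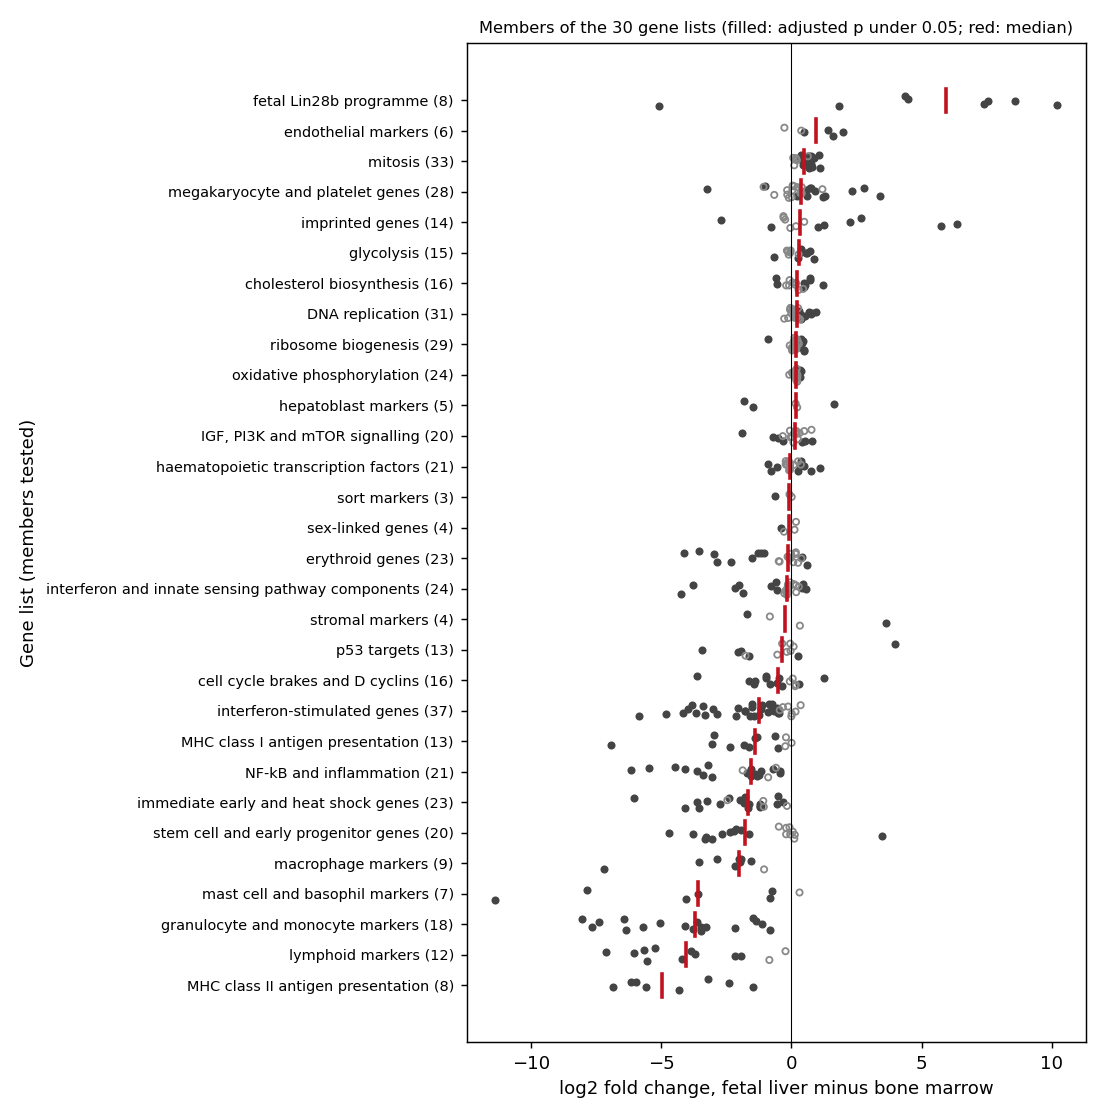
Log2 fold change, fetal liver minus bone marrow, of every tested member of the 30 gene lists, with filled points for adjusted p under 0.05 and red bars for list medians. Medians run from -4.96 for MHC class II presentation to 5.94 for the fetal Lin28b programme.

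In all, camera called 22 of the 30 lists, 13 lower and 9 higher in fetal liver. With an estimated correlation it called 0 (lowest adjusted p = 0.0794, with 11 lists at an unadjusted p under 0.05). fry, which does not compare a list with the other genes, called 23, and these were not all the same lists. It did not call megakaryocyte and platelet genes (fry adjusted p = 0.1655), erythroid genes (0.110) or oxidative phosphorylation (0.0598). Unlike camera, it called IGF, PI3K and mTOR signalling (0.0421), hepatoblast markers (0.0381), stromal markers (0.00174) and cholesterol biosynthesis (0.028).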

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

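One alternative, the floor at the control level, was chosen after the results were seen. The stricter filter, which tests fewer genes (9175), gave 1402 genes lower in fetal liver, and 790 at 2-fold or more, of which 203 were higher and 587 lower. Testing every probe set, of which there are more, gave 7237 calls, 3189 higher and 4048 lower, and 3298 at 2-fold or more, 847 higher and 2451 lower. Median centring gave 3649 higher and array weights 3169. Ordinary t statistics gave 2790 calls, 2615 of them shared, with 1316 higher. The cause of these last shifts was not tested. Leaving out single arrays gave 2865 to 4436 genes, 1268 to 2193 of them higher and 1597 to 2243 lower; the lowest higher counts came without bone marrow replicate 3 and, at 1337, without fetal liver replicate 3, with fewer samples in each fit. At 2-fold or more they gave 1555 to 1795. The replicate block gave 3847 genes, 3721 of them shared, and 21 lists. The list lost under that block was imprinted genes (camera adjusted p = 0.0550). Deviations of same-numbered arrays correlated at -0.08, 0.07 and -0.11. No pairing by number was seen, but so few arrays cannot exclude it. Of the 128 called named genes, 108 kept their call under every setting in which they were tested, and no named gene's call reversed. Most named genes were picked for a small p or a large change in these same data. A gene removed by a setting's filter was not counted as lost. The count is therefore no measure of stability over all genes.

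Camera's list calls held only with the preset correlation of 0.01. With an estimated correlation 0 of 30 lists passed. Adjusted p was 0.192 for interferon-stimulated genes, 0.113 for mitosis, 0.0794 for the fetal Lin28b programme and 0.0794 for granulocyte and monocyte markers. The medians of these lists stayed on their side of 0 under the 14 settings run for lists. Innate sensing components, MHC class II presentation and imprinted genes had estimated correlations below the preset (-0.0225, -0.0030 and -0.0374). They lost their calls too (adjusted p = 0.127, 0.0794 and 0.192). A correlation above the preset therefore cannot explain the loss in those lists. The other called lists had estimates above the preset. With an estimated correlation, camera also refers its statistic to the 4 residual degrees of freedom, which by itself raises p-values. Losing a call under that setting is therefore no measure of correlation between members, and the share of each was not tested. Quantile normalization called 18 lists, and leaving out single arrays 19 to 22. Other splits of the 6 arrays into 3 and 3 called 6 to 17 lists with the preset correlation. Each of these splits mixed the tissues unevenly. Part of the tissue difference remained between its groups, and part entered the spread within them. Their counts therefore do not show how many calls arise with no difference. The split by tissue called 4208 genes and 22 lists, against at most 0 genes and 17 lists in the other splits; 1 of the 10 splits, the tissue one, reached each real value, and 10 splits are too few for a share under 0.05. Low signal limits folds: 138 called genes lay at or below the control level in fetal liver alone and 30 in bone marrow alone.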

Other observations

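The gene name families, the tests on late granule genes and those on immediate early genes were chosen after the results were seen, and so was a condition that voids slopes on granulocyte markers, given below. Genes grouped by the shared start of their names, with at least 6 tested members, gave 286 families. Camera called 28, 12 higher and 16 lower in fetal liver, and 0 with an estimated correlation. Under quantile normalization the higher families Eif, Cops, Psmd, Snrnp, Nup, Polr and Psmc lost the call (camera adjusted p = 0.0514 to 0.210). Cops (0.0609) and Snrnp (0.0580) also lost it under median centring. All families called lower kept theirs under both scalings. Mitochondrial ribosomal protein genes were higher: 35 of 47 of the large subunit rose and 0 fell (median log2 fold change 0.40, adjusted p = 4.13e-07; adjusted p = 0.727 with an estimated correlation), and 18 of 29 of the small subunit (median 0.39, adjusted p = 5.43e-06; 0.727 with an estimated correlation). Both medians stayed above 0 under quantile normalization (0.35 and 0.39) and median centring (0.56 and 0.55). Timm genes of mitochondrial protein import rose in 9 of 14 cases. Homeobox genes of the Hox clusters were lower in 8 of 9 cases (median -2.65, adjusted p = 4.83e-04; adjusted p = 0.695 with an estimated correlation), with Hoxb3 falling from 241 ± 43.8 to 10.9 ± 4.73 (SD, n = 3) and Hoxb4 from 195 ± 30.7 to 31.6 ± 7.65. Klf transcription factors fell in 8 of 12 cases, led by Klf9 (2891 ± 429 to 156 ± 82.4), and in 6 under median centring. Schlafen genes fell in 5 of 7 cases, with Slfn2 at 1014 ± 337 in bone marrow and 10.5 ± 6.82 in fetal liver. The split by tissue was the 1 of 10 splits with as many families, and the highest other split called 25. The other splits keep part of the tissue difference, and 10 splits are too few for a share under 0.05.

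Lower interferon-stimulated genes in fetal liver could come from array scaling, from mature granulocytes in the bone marrow samples, or from tissue and age. Scaling was argued against: the weaker median under quantile normalization or median centring was -1.09, and the list kept its camera call under both. The granulocyte explanation met the value set for it in advance, a median slope of at least 0.5 on the granulocyte marker mean over the 3 bone marrow arrays: the slope of the 30 called members was 1.52 (95% bootstrap interval over genes 1.001 to 1.989). That slope rests on bone marrow replicate 1, since between replicates 2 and 3 it was -1.97 (-5.28 to 1.94). On replicate 1 the median member of the erythroid, lymphoid and mast cell lists was shifted too (-0.70, -0.84 and -0.56 log2 units). Macrophage and megakaryocyte lists were shifted the other way (0.20 and 0.21). The slope therefore cannot single out granulocytes. A condition added after the slopes were seen asks that the marker means of each pair of arrays differ by more than the typical gene does. Replicates 2 and 3 differed by 0.02 log2 units, against 0.16 for the typical gene, so the slope was set aside; without the condition it would count for granulocytes. With it, granulocytes cannot be told apart from tissue and age, which stay open, untested.

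High mature granulocyte transcripts might come from cells or free RNA of mature granulocytes in the bone marrow samples, although the lineage-negative gate would remove the cells. Of the 5 late granule genes Ngp, Camp, Ltf, S100a8 and S100a9, 4 lay above the 95th percentile of signal on every bone marrow array. Ltf was at percentile 93.8 on replicate 1. High rank is expected from either source, so this test cannot support such cells, and they cannot be told apart from expression in the sorted progenitors. Camp was at 7363 ± 1577 and S100a8 at 10310 ± 1328 (SD, n = 3). Mpo and Lyz2 of the same marker list had signals of 3144 ± 390 and 2559 ± 518 in fetal liver too. Expression by adult progenitors stays open, untested.

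Lower immediate early genes in fetal liver may reflect handling of the cells before lysis. Arrays of one tissue differed in the list mean by up to 1.71 log2 units, in fetal liver, against -1.98 between tissues, which lies between the lower and upper bounds set for the test, so handling and tissue cannot be told apart. For mature granulocytes in the bone marrow samples the slope on the granulocyte marker mean was -0.31 (95% bootstrap interval over genes -0.60 to 0.16). Such intervals hold the arrays fixed and do not measure the spread between them. The upper bound there and in the 3 pairs of arrays (0.03, 0.46 and -1.42) lay under 0.5. By the rule set for the test that would argue against granulocytes, without the condition added later. Replicates 2 and 3 fail that condition here too (0.02 against 0.16), so granulocytes stay open, and tissue stays open, untested.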
